A study of Mus musculus with 15 samples.

How the data were processed

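RNA and m6A were profiled in the mouse podocyte line MPC5 in 3 conditions of 5 samples. Per the labels, poly(A) RNA was fragmented, part was kept as input and part was pulled down with an antibody against m6A, and strand-marked libraries were sequenced in pairs. The submitters' processing notes name fastp 0.19.4, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1 and HOMER 4.10 without roles, and the peak caller is not given in the sources used here. Those notes name the human build GRCh38 for all 15 samples, although the cells are mouse. The coordinates were therefore checked against the RefSeq annotation of mouse build GRCm38.p6. Of 11591 tested genes 11190 (96.5%) had a unique symbol there, 11188 overlapped the gene of that symbol, 5084 (45.4%) shared its start or end exactly and 10202 (91.2%) lay within 100 bp of it at 1 end or both.

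The deposited RNA table holds, per the file headers, FPKM (fragments normalised to transcript length and library size) and whole-number counts, with 1 column of each kind per condition. The column names match the library names of the samples of no stated kind, and whether those were separate libraries or pooled input is not given in the sources used here. Depth was 54282720 counts for the control, 53655982 for the library labelled sh-METTL3 and 52807701 for the glucose library. The deposited peak lists, 1 per condition, give the authors' fold enrichment as a ratio of pulled-down to input RNA, with log10 p and log10 adjusted p values. The deposited differential peak tables, 1 per comparison, give the authors' log2 fold change with a p-value and an adjusted p, and hold peaks with a p under 0.05. The sign of each was checked against the ratio of the deposited fold enrichments, with 89.1%, 88.5% and 87.1% of the peaks found in both lists of the pair sharing it. The glucose table was deposited as sh-METTL3 over glucose, so its signs were turned. Apart from this check of signs, deposited fold enrichments are described within a list alone. Peak starts count from 0 in the deposited lists, since 2644, 3661 and 4317 peaks started 1 base before the start of their gene and 2, 2 and 2 at it, so 1 was added. Of the per-sample columns, 0 were left unused.

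The design fixed before the data were examined planned limma or edgeR on 6 input libraries and camera for gene lists. None of these tests was run, because the table holds 1 column per condition; the design's fallback for single libraries was used in their place. It takes log2 of (FPKM + 1) ratios over genes with a mean FPKM of at least 1 across the 3 libraries, and counts a gene as higher or lower at an absolute log2 ratio of at least 1, without subtraction of the all-gene median. Log2 ratios of named genes and lists have that median subtracted. For each of 32 fixed gene lists with at least 5 tested members, the median was placed among 10000 random lists of the same size drawn with seed 11 within 20 bins of mean expression, and percentiles outside 2.5 to 97.5 were counted. Lists on endothelial, mesangial, tubular and leukocyte markers and on histones had 0, 3, 4, 3 and 2 tested members and received no percentile. Ratios of count shares carry exact binomial intervals and peak shares Wilson intervals, both at 95%. The Wilson intervals treat peaks as independent and cover no spread between replicates. Under an alternative, a peak share outside its Wilson interval was labelled as moved. Peaks were shared when they overlapped by at least 1 bp on the same strand. Each peak was taken from its first to its last base, so an intron inside a peak counted as part of it. Genes with differential peaks of 1 direction were treated as lists in the RNA comparison of the same pair. No p-value of RNA was computed, and m6A enrichment per gene was not analysed here.

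Named genes followed a rule fixed beforehand. It takes Mettl3, S1pr1, Smad2 and Smad3 always, the 10 highest and 10 lowest genes with a mean FPKM of at least 5, and up to 2 members of each list per direction, by size of the ratio since no test was run. For peaks it takes those of the same 4 genes, the 5 highest and 5 lowest at an adjusted p under 0.05, and up to 3 per list in the ferroptosis, podocyte, TGF-beta and sphingosine lists. Among the highest and lowest genes and peaks, but not among list members, pseudogenes, predicted genes and genes with near-identical copies were skipped, and after the values were seen Gvin genes and the mitochondrial genes copied on chromosome 1 were added to those skipped there. Genes named for other reasons are marked as chosen after their values were seen, and examples of other cell types come from their lists. Some items that the rule takes are not reported here.

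The procedure was tested on a simulated pair of libraries, both drawn from the control counts with an assumed noise. That pair had no length trend and no shift in RNA makeup, so its calls of unchanged genes do not measure those of the real pair. List checks used independent noise on random genes, so they do not cover lists of genes that move together. Of genes simulated 4-fold higher 100% were called, of those 4-fold lower 76%, of those 3-fold higher 96% and of those 3-fold lower 70%, with 0 unchanged genes called. A simulated list of 25 genes shifted by 0.8 reached percentile 100, and 4% of 100 unshifted lists lay outside the limits. Removal of a planted length trend took Spearman's rho from 0.767 to 0.00904.

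Alternatives tried were a pseudocount of 0.1, no filter and a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, a filter on the 2 libraries compared, an overlap of 50% of both peaks, fold enrichment of at least 4 with an adjusted p under 0.001, peaks in genes with an FPKM of at least 1 in all 3 libraries, and adjusted p under 0.01 or a log2 fold change of at least 1 for differential peaks. Added after seeing the data were removal of the length trend by a running median over 50 length bins, protein-coding genes alone, random lists matched on length in 10 by 10 bins, results of single lists and counts of lists per comparison under quantile normalization and pseudocount 0.1, pseudocount 0.1 for RNA of genes with differential peaks, and unadjusted p for counts of differential peaks. Pseudocount 0.1 for the total of lists outside the range, and unadjusted p for RNA of genes with differential peaks, had been planned. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.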

Results

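The study measured N6-methyladenosine (m6A), a common internal mark of messenger RNA, together with RNA levels in MPC5, an immortalised mouse podocyte line; podocytes are the epithelial cells that line the filtration barrier of the kidney. The 15 samples fell into 3 conditions of 5 samples each: a control in standard medium, cells given a virus carrying an shRNA against METTL3, and cells given that virus and then added glucose (25 µmol/L as labelled) for 72 hours. That unit is printed as labelled and no value here checks it; high-glucose media are usually given in millimoles per litre, so the dose is uncertain. In each condition 2 samples were input RNA, 2 were RNA pulled down with an antibody against m6A, and 1 named neither kind. The RNA values came as 1 library per condition, with 54282720 counts for the control, 53655982 for the library labelled sh-METTL3 and 52807701 for the library labelled sh-METTL3 with glucose, called the glucose library from here on. With 1 library per condition there was no replicate spread, so no difference between conditions could be checked against it, and "higher" and "lower" describe these libraries alone. Intervals on ratios of counts are 95% exact binomial intervals, which compare libraries and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The control received no virus, so virus and shRNA were not separable, and no unmodified cells with added glucose were among the conditions.

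Mettl3, the catalytic subunit of the m6A writer complex and the target of the shRNA, was not lower in either library labelled sh-METTL3. Its level (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, mouse build GRCm38) was 2.34 FPKM in the control, 2.42 in the library labelled sh-METTL3 and 2.49 in the glucose library, from 989, 1028 and 1033 counts. The ratio of count shares to the control was 1.05 (0.963 to 1.15) for the library labelled sh-METTL3 and 1.07 (0.983 to 1.17) for the glucose library. These lower bounds leave no room for a ratio below 0.963 or 0.983 from counting error, so depth was not the limit. For this reason the libraries are named by their labels throughout, and no direction given here is a measured effect of less Mettl3 RNA.

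**Figure D1:**
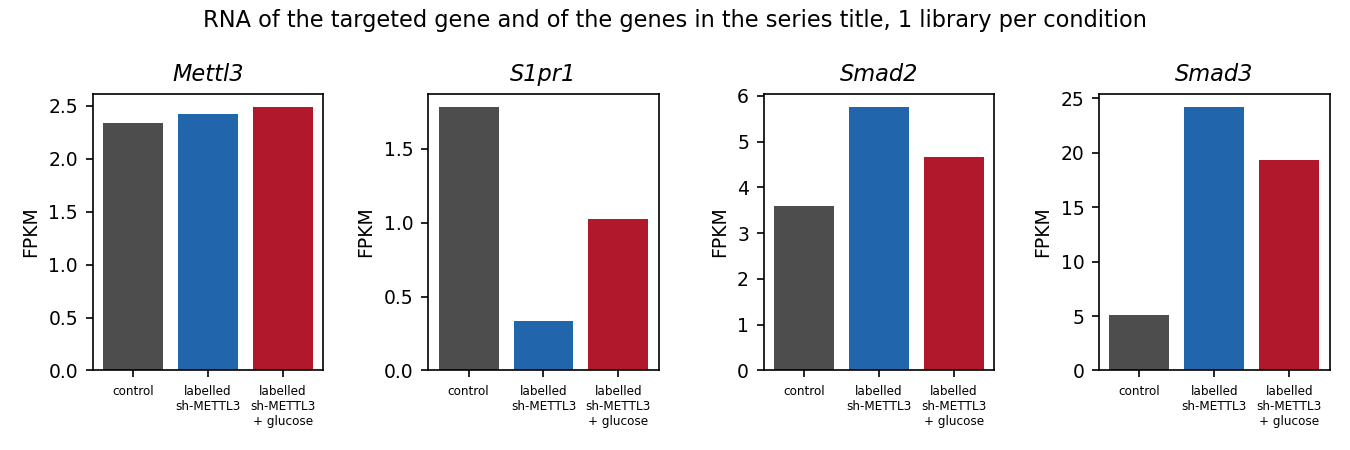
Deposited FPKM of Mettl3, S1pr1, Smad2 and Smad3 in the 3 libraries, 1 bar per library from 0. Mettl3 lay between 2.34 and 2.49 FPKM, S1pr1 was lowest in the library labelled sh-METTL3 (0.335), and Smad3 was 5.14 in the control against 24.2 and 19.3.

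The comparison of the library labelled sh-METTL3 with the control asks what the virus directed at METTL3 did to RNA and m6A, within the axis of Smad2, Smad3, METTL3 and S1PR1 named in the series title. S1pr1, a receptor for sphingosine 1-phosphate (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072), was lower, at 0.335 FPKM against 1.78 in the control, a ratio of count shares of 0.193 (0.151 to 0.243) from 86 and 451 counts. Smad3, which carries TGF-beta signals to the nucleus (ENSMUSG00000032402, chromosome 9, 63646767 to 63757994), was higher, at 24.2 against 5.14 FPKM, a ratio of 4.79 (4.58 to 5.01). Smad2 (ENSMUSG00000024563, chromosome 18, 76241580 to 76310963) stood at 5.77 against 3.60 FPKM, a ratio of 1.63. Medians of interferon and inflammatory genes were low and those of lipid synthesis genes high in the library labelled sh-METTL3, although Mettl3 itself was not lower there. Lcn2, an iron-binding protein of kidney injury, stood at 0.137 FPKM against 40.3 in the control, while Scd2, a fatty acid desaturase, stood at 467 against 49.9.

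Of 11591 genes tested, 1324 were at least 2-fold higher and 928 at least 2-fold lower, so 58.8% of the 2252 were higher. Here and below, such counts were made with 1 added to each FPKM, which shrinks the ratios of genes at low FPKM. Median-of-ratios scaling, which moved the all-gene median by -0.13, gave 1031 higher and 1251 lower genes, 45.2% higher, while protein-coding genes alone, a filter chosen after seeing the data, numbered 1217 higher and 514 lower, 70.3% higher. The median gene had a log2 ratio of 0.10, and every log2 ratio of RNA given from here on is relative to the median gene of its comparison. The genes with the highest ratios were Cntf, a neurotrophic cytokine (4.79), Inmt, a methyltransferase (4.58), the secreted protease Adamts1 (3.44), the water channel Aqp1 (3.42), Mfap3l (3.24), the secreted hormone Stc2 (3.13), Scd2 (3.10), Sult1d1 (3.06), the small GTPase Rhou (2.92) and the matrix protein Thbs1 (2.92). Cntf stood at 0.783 FPKM in the control and 51.9 in the library labelled sh-METTL3, and Inmt at 0.566 and 39.1. The genes with the lowest ratios included Lcn2 (-5.29), the interferon-induced Ifi27l2a (-4.25), the chemokine Ccl7 (-4.18), the retinal dehydrogenase Aldh1a1 (-3.66) and Trim30a (-3.50). The other lowest were Rn7sk (-4.93), Rmrp (-4.52), Lars2 (-4.19), Rpph1 (-4.00) and Snord55 (-3.50), of which all but Lars2 are small or structured RNAs that carry no regular poly(A) tail.

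Of 29 tested interferon-stimulated genes, which cells switch on against viruses, 20 were at least 2-fold lower, 0 higher and 9 between. Their median was -1.64, at percentile 0 of 10000 random lists matched on expression, a description of these libraries as are all such percentiles. Zbp1, a sensor of foreign nucleic acid (-3.21), and Ifi44 (-3.13) were the lowest, and Ifit2 (0.88) went the other way. Of 19 inflammatory and NF-kB genes, 14 were lower, 1 higher and 4 between, with a median of -2.36 at percentile 0; the cytokine Lif (1.03) was the higher one. Of the leukocyte markers, Csf1r stood at 0.442 FPKM in the control and 4.03 in the library labelled sh-METTL3, Cd14 at 2.11 and 5.08, and Cd68, which moved the same way as the inflammatory genes, at 2.59 and 1.88.

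Among 23 genes of cholesterol synthesis (SREBP2 targets), 10 were at least 2-fold higher and 0 lower, with a median of 0.88 at percentile 100. Idi1, an isomerase of isoprenoid synthesis, stood at 19.9 FPKM against 6.05. In fatty acid synthesis (SREBP1 targets) 8 of 12 were higher and 0 lower, with a median of 1.07 at percentile 100, Scd2 and the elongase Elovl6 (12.9 against 1.77 FPKM) in front. Immediate early genes, transcribed within minutes of a stimulus, were higher in 10 of 20 and lower in 1, with a median of 0.96 at percentile 100. The transcription factor Egr2 stood at 9.78 against 0.174 FPKM and the antiproliferative gene Btg2 at 60.5 against 9.67, while Klf4 (-1.26) was lower. Tubular epithelial markers moved with these groups, with Aqp1 at 36.9 against 2.29 FPKM, Lrp2 at 14.6 against 2.05, Cdh16 at 87.1 against 41.6 and Pax8 at 33.2 against 13.0.

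Ferroptosis, an iron-dependent death by lipid peroxidation, is named in the series title. Of 25 genes that restrain it, 7 were higher, 1 lower and 17 between, with a median of 0.14 at percentile 97.1, but 87.5 with length matching, and a median of 0.52 at percentile 99.8 after quantile normalization. Scd2 (3.10) and Scd1 (1.93) were the highest, and Hspb1, a small heat shock protein (142 against 768 FPKM), and the cystine transporter subunit Slc3a2 (-0.93) the lowest. Gpx4, which reduces lipid peroxides, stood at 101 against 156 FPKM and Slc7a11, the cystine transporter, at 1.97 against 1.82; both were singled out after their values were seen. Of 20 genes that promote ferroptosis, 3 were higher, 1 lower and 16 between, with a median of 0.29 at percentile 95.7. Keap1, the repressor of NRF2 (1.35), and the transferrin receptor Tfrc (0.94) were the highest, and the polyamine enzyme Sat1 (-1.14) the lowest. NRF2 targets, which answer oxidative stress, were higher in 5 of 18 and lower in 0, with a median of 0.48 at percentile 99.8, as Srxn1 (13.5 against 2.83 FPKM) and Osgin1 (8.65 against 1.77) show.

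Podocyte markers were higher in 8 of 18 and lower in 1, with a median of 0.83 at percentile 100. Kirrel, a slit diaphragm protein, stood at 45.1 against 8.61 FPKM and Synpo, an actin-binding protein of foot processes, at 8.59 against 1.19. Vegfa (6.65 against 20.5 FPKM) was the 1 counted as at least 2-fold lower with 1 added to each FPKM. Nphs1, the gene of nephrin (-0.98), came next among those tested. Its plain FPKM values, 1.37 against 3.35, were more than 2-fold apart. Among podocyte markers below the mean FPKM of 1, singled out after the values were seen, the transcription factor Wt1 had 338 counts in the control, 22 in the library labelled sh-METTL3 and 125 in the glucose library, and Foxc2 67, 22 and 60. TGF-beta and Smad genes were higher in 4 of 22 and lower in 2, with a median of 0.40 at percentile 99.0; the receptor Tgfbr2 (2.45) and Smad3 (1.94) were the highest, and Id3 (-1.57) and Id1 (-1.28) the lowest. Matrix and fibrosis genes were higher in 4 of 20 and lower in 4, with a median of 0.30 at percentile 99.6, or 94.2 among random lists matched on length too, and a median of 0.58 after quantile normalization. Thbs1 (2.92) and the protease Mmp14 (1.51) stood against Timp1 (-2.28) and smooth muscle actin, Acta2 (-2.19). In the sphingosine 1-phosphate pathway 5 of 19 were higher, among them the kinase Sphk2 (1.85) and the desaturase Degs1 (1.48), and 1, S1pr1 (-1.16), was lower, with a median of 0.06 at percentile 67.3.

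Genes of the unfolded protein response and of ATF4 were lower in 11 of 24 and higher in 1, with a median of -0.88 at percentile 0.10; the chaperone Hspa5 stood at 119 against 780 FPKM and the stress gene Nupr1 at 9.68 against 58.6. Cytosolic ribosomal protein genes were lower in 25 of 30 and higher in 0, with a median of -1.32 at percentile 0, Rps19 (-1.67) and Rps27a (-1.59) the lowest. The random lists of such highly expressed genes had a median of -0.67 themselves, and after quantile normalization the ribosomal median was -0.54 at percentile 0.09. Mitochondrially encoded genes were higher in 7 of 13 and lower in 0, with a median of 1.06 at percentile 100, mt-Cytb (2.60) the highest and mt-Co1 (-0.92) the lowest. The mitochondrial ribosomal RNAs, outside this list, were lower, mt-Rnr1 at 76.5 against 570 FPKM and mt-Rnr2 at 103 against 408. Counts of mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l lay within 5% of those of a copy on chromosome 1, so their reads were not assigned to 1 place. Of 8 nuclear noncoding RNAs 5 were lower, with a median of -2.12 at percentile 0. RNA makeup differed along with these groups. CT010467, an RNA resembling 18S ribosomal RNA, took 2.29% of the control's counts, 0.0834% of those of the library labelled sh-METTL3 and 0.0926% of those of the glucose library. Across genes the ratio increased with gene length (Spearman rho 0.42 over 11591 genes, which are not independent replicates). The median log2 ratio, relative to the median gene, went from -0.70 in the shortest decile to 0.45 in the longest. Gene length was inferred from the counts and FPKM of these same libraries.

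Writers of m6A had a median of -0.06 (percentile 30.8), with Rbm15b at 1.25 and Rbm15 at -1.28, and m6A erasers and readers 0.29 (95.5), with Ythdc2 at 1.12. Actin and focal adhesion genes had a median of 0.04 (99.4, or 67.6 with length matching), and 0.69 after quantile normalization. Proliferation genes had 0.04 (97.45), or 0.36 (99.1) after quantile normalization, with Kif11 at 1.65 and Mki67 at 1.54. Medians inside the central 95% of random lists were also found for glycolysis (-0.38, percentile 37.0), glucose-responsive genes (-0.18, 36.1), oxidative phosphorylation (-0.40, 44.8), p53 targets (-0.14, 28.9), hypoxia targets (-0.09, 49.6), autophagy (-0.15, 62.9) and apoptosis (0.18, 87.0). Quantile normalization moved glycolysis to -0.00, oxidative phosphorylation to -0.06, hypoxia targets to -0.02, the sphingosine pathway to 0.16, m6A writers to -0.18 and autophagy to the other side, 0.09, all inside that range. Of the 27 lists with at least 5 tested members, 9 lay above and 5 below the central 95%.

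**Figure D2:**
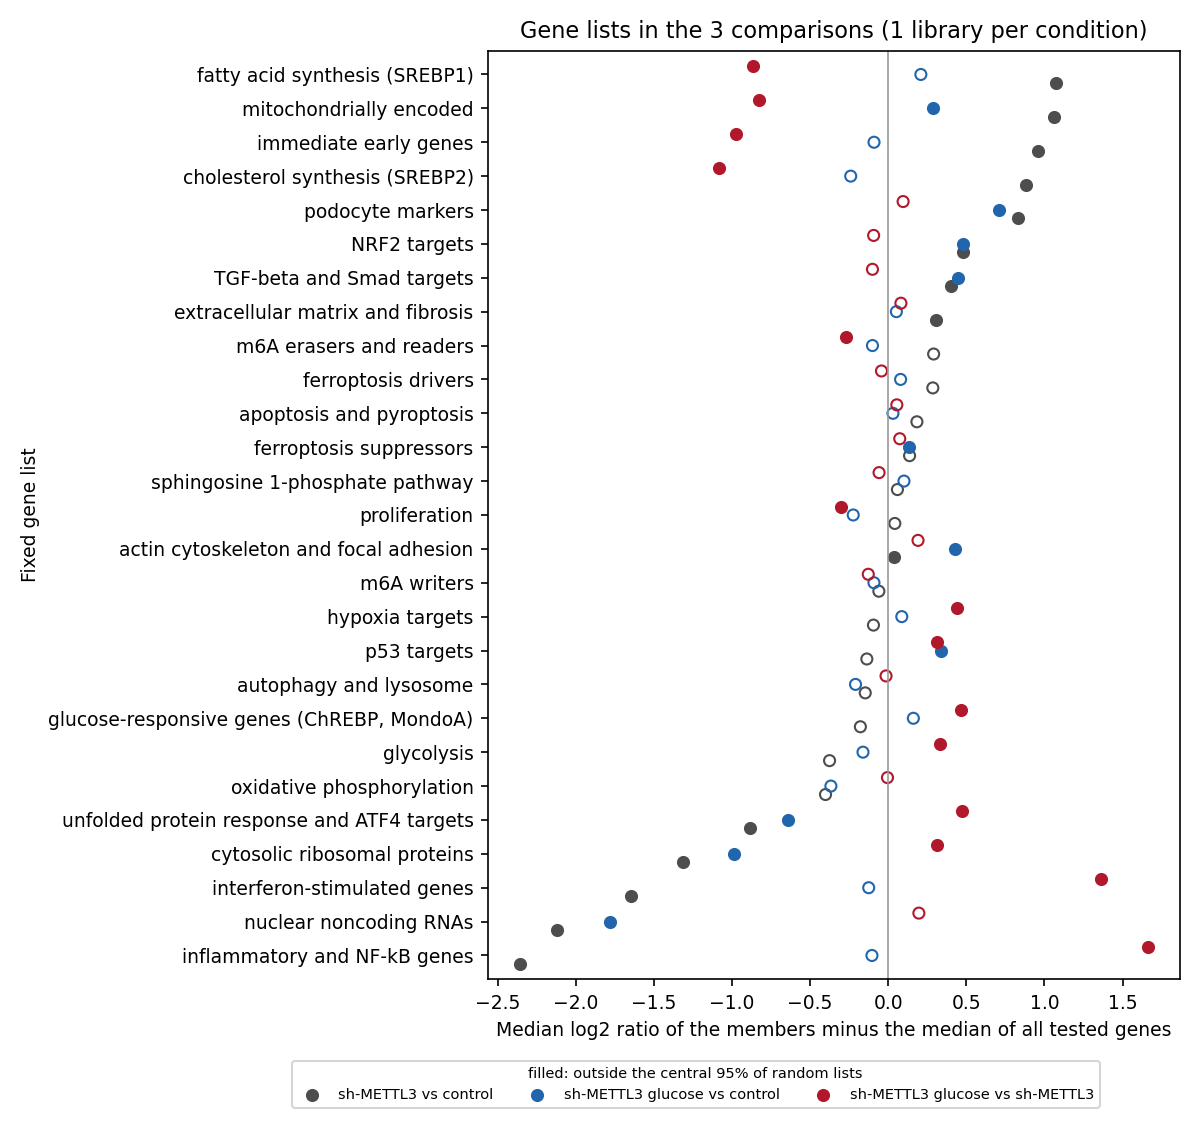
Median log2 ratio of each fixed list minus the all-gene median, in the 3 comparisons, 1 point per list and comparison, filled where it lay outside the central 95% of random lists. Interferon-stimulated genes stood at -1.64 in the library labelled sh-METTL3 against the control, -0.12 in the glucose library against the control and 1.36 between the libraries with and without glucose.

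The authors' peak lists held 22498 m6A peaks in the control, 24626 in the condition labelled sh-METTL3 and 27480 with glucose, in 11204, 11571 and 11898 genes. At an adjusted p under 0.05 they held 18956, 20741 and 22423. With a fold enrichment of at least 4 and an adjusted p under 0.001 they held 10542, 11355 and 10667, so glucose no longer had the most. Over all peaks, the 3'UTR shares were 52.6%, 51.2% and 50.1%, and the 5'UTR shares 14.7%, 15.3% and 17.4%. Of the control peaks, 84.1% (83.6 to 84.6, Wilson interval) had a peak in the list labelled sh-METTL3, and 79.1% (78.6 to 79.6) of the latter had one in the control. Wilson intervals here and below treat peaks as independent, although peaks outnumbered genes, and cover no spread between replicates. With Mettl3 RNA not lower, the authors' deposited table for sh-METTL3 against control held 2007 differential peaks at an adjusted p under 0.05, 1527 higher and 480 lower, 76.1% higher. By place, 80.6% of 279 peaks in 5'UTRs, 82.9% of 543 in coding exons and 72.1% of 1103 in 3'UTRs were higher in the authors' deposited table.

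In S1pr1, the authors' deposited table gave the 3'UTR peak at 115711567 to 115712015 on chromosome 3 a log2 fold change of -1.89 (p = 0.0214, adjusted p = 0.116) in sh-METTL3 against control. For Smad3, the authors' deposited table listed 3'UTR peaks at -0.14 (63648414 to 63650361, adjusted p = 0.0324) and -0.13 (63646767 to 63648115, adjusted p = 0.193). Smad2 had a 3'UTR peak at -0.36 (76302466 to 76304970, adjusted p = 0.106) in the authors' deposited table, and no Mettl3 peak was listed there. Highest in the authors' deposited table were peaks in Prr13 (5.20), Ube2s (2.27), Naa15 (1.79), Atp6v0c (1.73) and Kif21b (1.71). Lowest in the authors' deposited table were peaks in Ppp1cc (-3.78), Gon4l (-2.23), Idi1 (-2.07), Ptprj (-2.06) and Gps1 (-1.58). Podocyte markers held 5 differential peaks in the authors' deposited table, 5 higher and 0 lower, among them Ezr (0.58), Podxl (0.67) and Nes (0.38). Ferroptosis suppressors held 6 higher and 2 lower in the authors' deposited table, with Por at 0.96 and Gclm at -1.41, and drivers 2 higher and 1 lower, with Ncoa4 at 0.87 and Fads1 at -0.78. TGF-beta and Smad genes held 6 higher and 7 lower peaks in the authors' deposited table, with Id2 at 0.54 and Id3 at -0.75. The sphingosine pathway held 1 higher peak in the authors' deposited table, in Sgpl1 (0.33), and 2 lower ones, in Plpp2 (-0.38) and Sptlc2 (-0.36).

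Of genes with higher peaks alone, 1217 were tested, with a median relative log2 ratio of RNA of 0.12 at percentile 100, or 93.1 with length matching. Of genes with lower peaks alone, 389 were tested, with a median of 0.30 at percentile 100. Peak and RNA values may share input libraries, so the measures are not independent.

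The comparison of the glucose library with the control asks where cells that had the virus and added glucose stood relative to cells with neither, and Mettl3 was again not lower (2.49 against 2.34 FPKM). S1pr1 was lower, at 1.02 against 1.78 FPKM, a ratio of count shares of 0.579 (0.494 to 0.677), and Smad3 higher, at 19.3 against 5.14 FPKM, a ratio of 3.78 (3.61 to 3.96). Smad2 stood at 4.66 against 3.60 FPKM, a ratio of 1.31. Medians of podocyte, actin and NRF2 genes were higher, with 7 of 18, 6 of 22 and 5 of 18 at least 2-fold higher. In each of these lists 0 were at least 2-fold lower, and interferon genes were close to the control. Synpo stood at 11.7 against 1.19 FPKM and Tgfbr2 at 19.9 against 2.75.

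Here 956 genes were at least 2-fold higher and 426 lower, 69.2% of 1382, with a median gene at 0.16. Median-of-ratios scaling moved that median by -0.19 and gave 594 higher and 759 lower, 43.9%, while quantile normalization moved it by -0.13 and gave 618 and 503, 55.1%. Protein-coding genes alone numbered 894 higher and 171 lower, 83.9%. Highest were Filip1l (2.51), Cdc42ep1 (2.43), Synpo (2.39), Tgfbr2 (2.32), Ehd2 (2.29), Ahnak (2.25), the taurine transporter Slc6a6 (2.15), the receptor Notch2 (2.14), Irgm2 (2.11) and the focal adhesion adaptor Bcar1 (2.11). Lowest were Rn7sk (-4.78), Snord55 (-4.71), Lars2 (-4.17), Rmrp (-4.07), Rpph1 (-3.31), Mir6960 (-3.17), Snord83b (-3.05), Snora31 (-2.94), Mir6953 (-2.87) and mt-Rnr1 (-2.80), mostly small RNAs inside other genes or RNAs without a regular poly(A) tail. Cytosolic ribosomal protein genes had a median of -0.99 at percentile 0, or -0.38 after quantile normalization, with 3 of 30 at least 2-fold lower, and nuclear noncoding RNAs -1.78 at percentile 0, with 5 of 8 lower. Gene length and the ratio had a Spearman rho of 0.40 across genes.

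Podocyte markers were higher in 7 of 18 and lower in 0, with a median of 0.71 at percentile 100, Synpo and Nes (55.0 against 14.5 FPKM) the highest and Nphs1 (-0.77) the lowest. Actin and focal adhesion genes were higher in 6 of 22 and lower in 0, with a median of 0.43 at percentile 100, or 0.84 after quantile normalization, the cross-linker Flna (1.30) and Vcl (1.27) the highest. TGF-beta and Smad genes were higher in 3 of 22 and lower in 0, with a median of 0.45 at percentile 99.9. NRF2 targets were higher in 5 of 18, with a median of 0.48 at percentile 99.97, Srxn1 (1.37) and Gsta4 (1.25) the highest. Ferroptosis suppressors were higher in 1 of 25 and lower in 1, with a median of 0.13 at percentile 98.5, but 92.4 with length matching and 0.09 at 77.5 after quantile normalization. Nfe2l2, the gene of NRF2 (0.90), and Gclc (0.82) stood against Hspb1 (-1.96). Ferroptosis drivers were higher in 4 of 20 and lower in 0, with a median of 0.08 at percentile 82.5, the glutathione-degrading enzyme Chac1 (1.77) and the metal transporter Slc39a14 (1.35) the highest. The p53 targets had a median of 0.34 at percentile 98.9, with the stress cytokine Gdf15 at 1.08 and Fas at -1.11. Mitochondrially encoded genes were higher in 4 of 13 and lower in 1, with a median of 0.29 at percentile 99.98, or 1.08 after quantile normalization, mt-Cytb (1.67) against mt-Atp8 (-1.63). Genes of the unfolded protein response and ATF4 were lower in 7 of 24 and higher in 3, with a median of -0.64 at percentile 0.45, or -0.26 at 3.65 after quantile normalization.

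Interferon-stimulated genes were lower in 0 of 29 and higher in 0, with a median of -0.12 at percentile 37.0, and inflammatory genes higher in 3 of 19 and lower in 1, with a median of -0.10 at percentile 69.3. C3, the central complement protein (141 against 41.5 FPKM), and Nfkbia, an inhibitor of NF-kB (55.0 against 208), went opposite ways. Cholesterol synthesis had a median of -0.24 (percentile 18.1), with Insig1 at -1.89, fatty acid synthesis 0.21 (97.1, or 0.43 at 99.1 after quantile normalization), matrix genes 0.05 (94.6, or 0.50 at 99.9 after quantile normalization) and immediate early genes -0.09 (79.7). Medians inside the central 95% were found for m6A writers (-0.09, percentile 22.5), erasers and readers (-0.10, 51.3), the sphingosine pathway (0.10, 78.4), glycolysis (-0.16, 71.2), glucose-responsive genes (0.16, 84.7), oxidative phosphorylation (-0.37, 39.5), proliferation (-0.22, 69.3), hypoxia targets (0.09, 85.2), autophagy (-0.21, 47.3) and apoptosis (0.03, 67.7). Quantile normalization turned the medians of glycolysis (0.11), proliferation (0.07), autophagy (0.06), inflammatory (0.03) and immediate early genes (0.20) positive. It moved oxidative phosphorylation to -0.04, interferon genes to -0.01, erasers and readers to -0.05, writers to -0.23, ferroptosis drivers to 0.15, the sphingosine pathway to 0.23, glucose-responsive genes to 0.33, hypoxia targets to 0.18 and apoptosis to 0.11, with all these medians inside the central 95%. Of the 27 lists, 7 lay above and 3 below the central 95%. Of the tubular markers, Lrp2 stood at 7.86 against 2.05 FPKM, Pax8 at 30.1 against 13.0, Cdh16 at 46.2 against 41.6 and Aqp1 at 3.42 against 2.29.

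In the authors' deposited table for sh-METTL3 with glucose against control, 6517 peaks had an adjusted p under 0.05, 3620 higher and 2897 lower, 55.5% higher. By place, 72.4% of 967 peaks in 5'UTRs, 58.0% of 1396 in coding exons, 88.3% of 94 in introns and 49.6% of 3805 in 3'UTRs were higher in the authors' deposited table. Of the control peaks 82.9% (82.4 to 83.4) had a peak in the glucose list, and 68.3% (67.8 to 68.9) of the glucose peaks had one in the control. The S1pr1 3'UTR peak (115711567 to 115711866) had a log2 fold change of -3.35 (adjusted p = 0.0148) in the authors' deposited table, and the main Smad3 3'UTR peak -0.56 (adjusted p = 3.3e-09). A Mettl3 3'UTR peak (52294871 to 52295020) stood at 1.76 (adjusted p = 1.2e-04) in the authors' deposited table, in a transcript whose level was not lower. Its fold enrichment within the glucose list was 2.71, and the control list held no Mettl3 peak. Highest peaks of the authors' deposited table lay in Prr13 (5.29), Eif4h (4.01), Bcl10 (3.39), Ap2m1 (3.30) and Usp7 (3.09), and lowest in Polr1d (-5.36), Tom1 (-5.01), Gps1 (-4.75), Tbl3 (-3.06) and Ubl4a (-2.75). TGF-beta and Smad genes held 4 higher and 14 lower peaks in the authors' deposited table, with Id2 at 0.99 and Id3 at -0.92. Ferroptosis suppressors held 11 higher and 7 lower peaks in the authors' deposited table, and drivers 8 and 4, with Tfrc at 2.13 and Chac1 at -1.18. Podocyte markers held 11 higher and 4 lower in the authors' deposited table, with Tjp1 at 1.37, and the sphingosine pathway 5 and 4, with the ceramide synthase Cers6 at 2.61 and Plpp2 at -0.61. RNA of genes with higher peaks alone had a median of -0.10 (2263 genes, percentile 0), and RNA of those with lower peaks alone 0.36 (1910 genes, percentile 100). Enrichment is a ratio over input RNA, which the RNA values may share. Opposite directions of peak and RNA therefore do not by themselves show an effect of m6A on RNA.

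The comparison of the glucose library with the library labelled sh-METTL3 addresses the addition of glucose on top of the virus, with Mettl3 at 2.49 and 2.42 FPKM, a ratio of count shares of 1.02 (0.936 to 1.11). S1pr1 was higher with glucose, at 1.02 against 0.335 FPKM, a ratio of 3.00 (2.34 to 3.88) from 254 and 86 counts, Smad3 had a ratio of 0.789 and Smad2 of 0.802. Most inflammatory and interferon genes were at least 2-fold higher with glucose. Medians of cholesterol, fatty acid and immediate early genes were lower. At least 2-fold lower were 12 of 23, 4 of 12 and 10 of 20 of them, and at least 2-fold higher 0, 0 and 2. Against the control, their medians were -0.24, 0.21 and -0.09 in the glucose library. In the library labelled sh-METTL3 they were 0.88, 1.07 and 0.96. With 1 library per condition, a fall with glucose cannot be told apart from a difference of the library labelled sh-METTL3 alone. Lcn2 stood at 61.9 against 0.137 FPKM, C3 at 141 against 4.47, and Fosb, an immediate early transcription factor, at 0.698 against 29.5.

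In this pair 326 genes were at least 2-fold higher and 214 lower, 60.4% of 540, with a median gene at 0.06. Highest were Lcn2 (5.73), C3 (4.64), the nitric oxide synthase Nos2 (3.76), Ccl7 (3.61), Aldh1a1 (3.41), Ifi27l2a (3.39), Sprr1b (3.31), the platelet chemokine Ppbp (3.26), Ccn5 (3.18) and Trim30a (3.07). Lowest were Fosb (-4.22), Cntf (-3.81), Sult1d1 (-3.40), Fos (-3.31), Aqp1 (-3.15), Inmt (-2.91), Arc (-2.88), Insig1 (-2.56), Scd2 (-2.39) and Hmgcs1 (-2.27), the last a synthase of the sterol pathway.

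Interferon-stimulated genes were higher in 24 of 29 and lower in 0, with a median of 1.36 at percentile 100, Zbp1 (2.65) and Oas3 (2.22) the highest. Inflammatory and NF-kB genes were higher in 15 of 19 and lower in 0, with a median of 1.66 at percentile 100. Cholesterol synthesis genes were lower in 12 of 23 and higher in 0, with a median of -1.08 at percentile 0, and fatty acid synthesis genes lower in 4 of 12, with a median of -0.87 at percentile 0, Elovl6 (-2.08) after Scd2. Immediate early genes were lower in 10 of 20 and higher in 2, with a median of -0.98 at percentile 0, Klf4 (1.62) and Klf2 (1.23) going the other way. Proliferation genes were lower in 4 of 28 and higher in 0, with a median of -0.30 at percentile 0, Mki67 (25.1 against 69.5 FPKM) and Cenpe (4.96 against 14.4) the lowest. Of the tubular markers, Aqp1 stood at 3.42 against 36.9 FPKM, Cdh16 at 46.2 against 87.1, Lrp2 at 7.86 against 14.6 and Pax8 at 30.1 against 33.2, and of the leukocyte markers Cd68 at 5.22 against 1.88, Csf1r at 1.00 against 4.03 and Cd14 at 4.61 against 5.08.

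Glucose-responsive genes were higher in 2 of 10 and lower in 0, with a median of 0.46 at percentile 99.96; they were Txnip, a brake on glucose uptake (291 against 78.7 FPKM), and Arrdc4 (0.98), the former also at 313 in the control. Glycolysis genes were higher in 2 of 20, Hk2 (1.32) and Slc2a1 (0.95), with a median of 0.33 at percentile 99.9, or 0.13 at 85.0 after quantile normalization. Hypoxia targets had a median of 0.44 at percentile 99.97, with Egln3 at 1.36 and Vegfa at 1.21. Genes of the unfolded protein response and ATF4 were higher in 5 of 24 and lower in 0, with a median of 0.47 at percentile 100, Chac1 (1.64) and Nupr1 (1.37) the highest. The p53 targets were higher in 3 of 20, with a median of 0.31 at percentile 99.9, the cell cycle inhibitor Cdkn1a at 1.55 and Btg2 at -1.93. Ribosomal protein genes had a median of 0.31 at percentile 99.3, or 0.18 at 95.4 after quantile normalization. Mitochondrially encoded genes were lower in 3 of 13, with a median of -0.83 at percentile 0, or -0.36 after quantile normalization, mt-Atp8 (-2.19) the lowest. Erasers and readers of m6A had a median of -0.27 at percentile 1.18, or 5.64 with length matching, Fmr1 (-1.08) and Ythdf3 (-1.05) the lowest.

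Ferroptosis suppressors had a median of 0.07 (percentile 61.3), with 3 of 25 lower, Scd2 (-2.39) and Scd1 (-1.78) the lowest, and drivers -0.04 (33.3), with Chac1 the 1 of 20 higher. Medians inside the central 95% were also found for m6A writers (-0.13, percentile 18.2), podocyte markers (0.10, 74.6, or 0.03 after quantile normalization), TGF-beta and Smad genes (-0.10, 12.6), matrix genes (0.08, 64.4), the sphingosine pathway (-0.06, 27.4), oxidative phosphorylation (-0.00, 24.5), NRF2 targets (-0.09, 11.5), actin and focal adhesion (0.19, 84.6, or 98.2 with length matching), autophagy (-0.01, 29.2), apoptosis (0.06, 68.4) and nuclear noncoding RNAs (0.20, 81.0). Of the 27 lists, 8 lay above and 6 below the central 95%. Vegfa was the 1 podocyte marker at least 2-fold higher, and Id1 (1.80) had the highest ratio of the TGF-beta list.

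The authors' deposited table for the condition labelled sh-METTL3 with and without glucose held 3332 peaks at an adjusted p under 0.05, 1520 higher and 1812 lower with glucose, 45.6% higher. With a log2 fold change of at least 1 as well, the majority turned, with 412 higher and 289 lower in the authors' deposited table, 58.8% higher. By place, 69.7% of 472 peaks in 5'UTRs, 40.7% of 565 in coding exons, 83.3% of 60 in introns and 40.1% of 2098 in 3'UTRs were higher in the authors' deposited table. Of the peaks labelled sh-METTL3, 83.0% (82.5 to 83.5) had a peak in the glucose list, and 72.6% (72.1 to 73.2) of the glucose peaks had one in the list without glucose. Both Mettl3 peaks of the authors' deposited table were higher with glucose, the 3'UTR peak (52294871 to 52295050) at 1.20 (adjusted p = 0.00813) and an intronic peak (52303725 to 52303904) at 1.15 (adjusted p = 0.139). Both were weak within the glucose list, with fold enrichments of 2.71 and 2.08 against a list median of 4.81. Neither other list held a Mettl3 peak. S1pr1 had a 5'UTR peak (115712194 to 115713000) at -0.62 (adjusted p = 0.168), Smad3 a 3'UTR peak at -0.42 (adjusted p = 4.2e-05) and Smad2 a 3'UTR peak at 0.38 (adjusted p = 0.0977) in the authors' deposited table. Among the highest peaks of the authors' deposited table were those in Gon4l (3.24), Pcnx3 (2.81), Arhgef2 (2.68) and Anapc5 (2.62), and the lowest lay in Tom1 (-4.41), Mat2a (-2.43), Timm23 (-2.15), Eno1 (-1.99) and Oser1 (-1.79). Ferroptosis suppressors held 6 higher and 5 lower peaks in the authors' deposited table, with Fads2 at 0.50 and Scd2 at -0.64, and drivers 7 and 4, with Tfrc at 1.97. Podocyte markers held 5 higher and 2 lower in the authors' deposited table, with Myo1e at 1.14, TGF-beta and Smad genes 6 and 10, with Smad7 at -1.04, and the sphingosine pathway 3 and 1, with Cers6 at 2.02. RNA of genes with higher peaks alone had a median of -0.06 (1141 genes, percentile 0), and RNA of those with lower peaks alone 0.03 (1368 genes, percentile 99.98). Here too, peak and RNA values may share input libraries and are not independent.

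**Figure D3:**
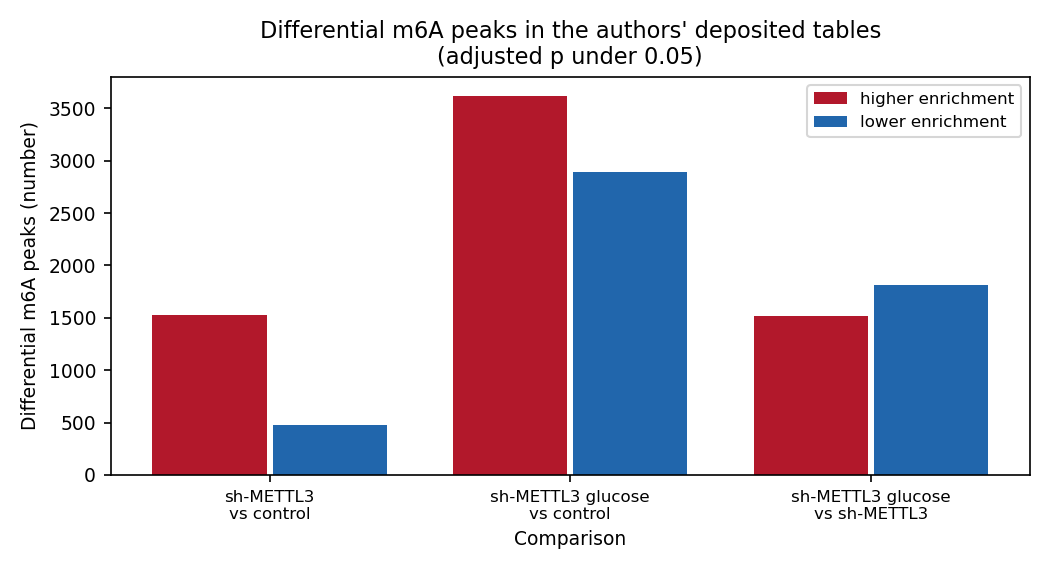
Number of differential m6A peaks at an adjusted p under 0.05 in the authors' deposited tables, higher and lower, for each comparison. Higher peaks numbered 1527, 3620 and 1520, and lower peaks 480, 2897 and 1812.

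On the mitochondrial chromosome, singled out after the values were seen, m6A enrichment between 7013 and 10173, from mt-Co2 through mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd3 to mt-Nd4l, differed from the rest. In sh-METTL3 against control the authors' deposited table listed 6 peaks there with a median log2 fold change of -8.89 (-9.58 to -5.64), and 2 outside with a median of -0.12 (-0.53 to 0.29). With glucose against control the authors' deposited table gave -3.60 (-4.03 to -3.29) for 5 peaks inside and 1.06 (0.60 to 1.54) for 9 outside. Between the conditions with and without glucose the authors' deposited table gave 5 (4.15 to 5.69) for 4 inside and 0.97 (0.82 to 1.60) for 7 outside. The control list held 6 peaks in this part, the list labelled sh-METTL3 0 and the glucose list 3. Within the control list the median fold enrichment of this part was 105, against 5.99 for the whole list. A copy of mitochondrial sequence lies on chromosome 1 (24611535 to 24616197), and 5 of 7 copied genes had counts within 5% of their copy in all 3 libraries, so reads of this part were not assigned to 1 place.

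**Figure D4:**
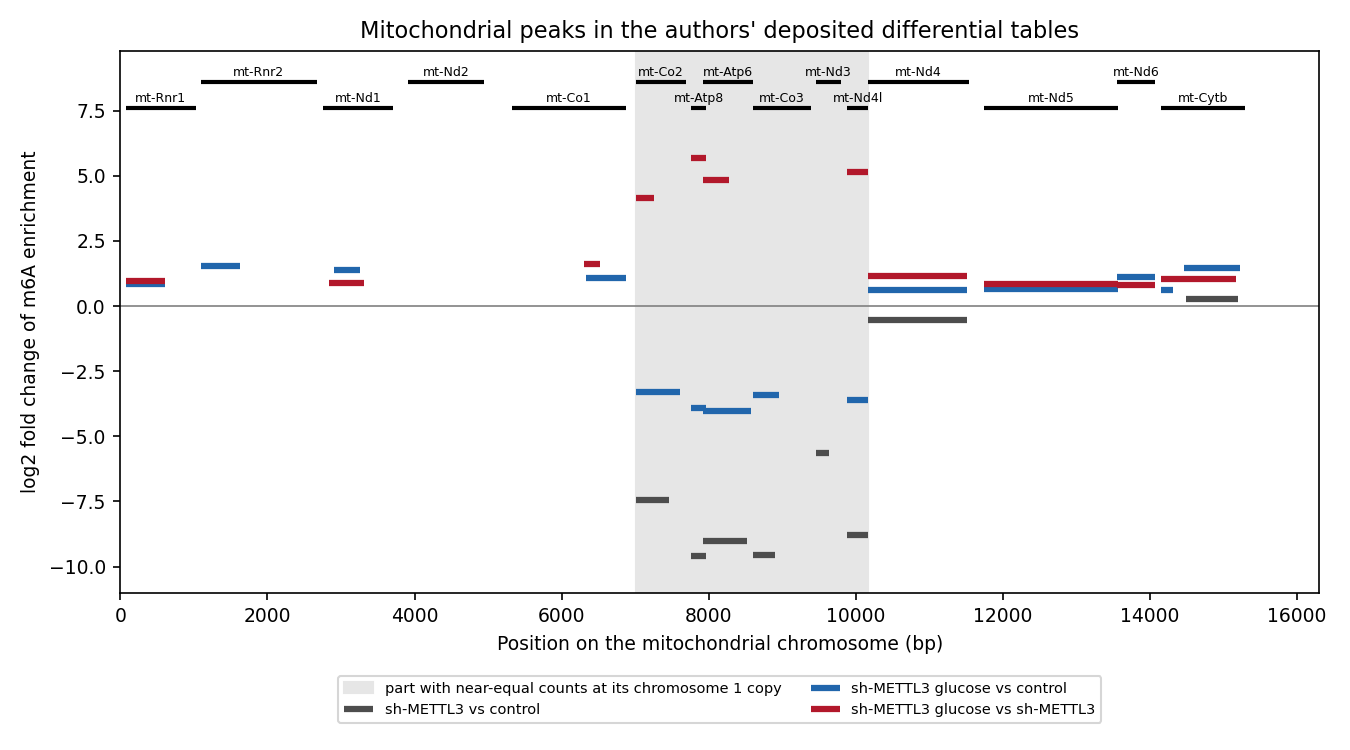
Log2 fold change of m6A enrichment along the mitochondrial chromosome in the authors' deposited tables, 1 bar per peak over its position. Between 7013 and 10173 the peaks of sh-METTL3 against control lay from -9.58 to -5.64, while the 2 outside lay at -0.53 and 0.29.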

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

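Unadjusted p for counts of peaks, the length matching, the length trend, the protein-coding filter, pseudocount 0.1 for RNA of genes with differential peaks and the alternatives for lists, except pseudocount 0.1 for their total outside the range (39 against 38), were chosen after seeing the data. Of 85 alternatives for the main counts and shares, 50 stayed within their limits, 34 moved and 1 lost its side of the threshold. These labels compare totals and shares, not which direction held the majority, and that turned in 4 cases: median-of-ratios scaling of sh-METTL3 against control (45.2% higher) and of glucose against control (43.9%), a mean FPKM of at least 5 for the former, and glucose against sh-METTL3 peaks with a log2 fold change of at least 1 (58.8% in the authors' deposited table). The cause was not tested, except that stricter thresholds and filters leave fewer genes or peaks by construction. Genes at least 2-fold apart numbered 1332 (sh-METTL3 against control, now 663 higher and 669 lower), 721 (glucose against control) and 297 (glucose against sh-METTL3) at a mean FPKM of at least 5. With a pseudocount of 0.1 they numbered 2383 (glucose against control) and 971 (glucose against sh-METTL3). Shares of peaks are given in the order control in sh-METTL3, sh-METTL3 in control, control in glucose, glucose in control, sh-METTL3 in glucose and glucose in sh-METTL3. With an overlap of 50% of both peaks they were 56.9%, 52.0%, 52.6%, 43.0%, 51.4% and 46.0%. With the stricter peaks they were 86.1%, 83.5%, 76.6%, 76.4%, 78.4% and 80.8%, from 10542, 11355 and 10667 peaks. In expressed genes they were 86.2%, 80.8%, 89.6%, 67.1%, 89.3% and 71.4%, from 14727 control and 15953 sh-METTL3 peaks. Differential peaks at an adjusted p under 0.01 numbered 1311 (sh-METTL3 against control) and 2217 (glucose against sh-METTL3), and with a log2 fold change of at least 1 as well as adjusted p under 0.05 they numbered 254, 1706 and 701. At an unadjusted p under 0.05, sh-METTL3 against control had 3518. RNA of genes with higher peaks alone in sh-METTL3 against control, at 0.12, dropped to percentile 93.1 with length matching. Of the list results, 80 kept their side with pseudocount 0.1 (1 moved outside), 73 with quantile normalization (4 out, 4 in) and 76 with length matching (1 out, 4 in). No paired analysis was possible because the table holds 1 column per condition and no replicate columns. The replicate block, the fit without trend, the adjusted p with a fold threshold for genes, the leaving out of each library and the estimated correlation between genes were not run for the same reason. Depth limits S1pr1 most among the 4 genes followed throughout, with 86 counts in the library labelled sh-METTL3.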

Other observations

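All tests of explanations given here were chosen only after the results they concern were seen. Of the endothelial markers 0 of 13 reached a mean FPKM of 1, whereas the tubular markers Cdh16 (41.6, 87.1 and 46.2 FPKM in the control, the library labelled sh-METTL3 and the glucose library) and Pax8 (13.0, 33.2 and 30.1) stood well above it. Among mesangial and pericyte markers Pdgfrb stood at 0.554, 4.01 and 2.12 FPKM in the same order, Notch3 at 2.09, 0.696 and 4.82, and Mcam at 8.15, 3.73 and 7.88. Of 15 replication-dependent histone genes, listed for RNA with poor poly(A) tails, 2 reached a mean FPKM of 1. H2bc4 stood at 10.9, 2.26 and 6.34 FPKM and H1f2 at 12.4, 11.3 and 20.2. Long nuclear RNAs went with neither group of libraries, with Malat1 at 60.5, 69.2 and 32.7 FPKM and Neat1 at 8.30, 8.58 and 6.57.

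Mettl3 was not lower in the libraries labelled sh-METTL3. Labels swapped between control and knockdown libraries would leave the control well below the others, but the lowest of the 3 FPKM values was 93.8% of the highest. Too few reads do not account for it, since the lower bound of the ratio of count shares was 0.963, and with the length trend removed the log2 ratio was -0.20, far from a 2-fold fall. A knockdown seen in protein alone, a weak one, or an exchange with a sample outside the series may remain, and no value here decides among them.

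Interferon and NF-kB genes were low in the library labelled sh-METTL3 alone, though Mettl3 was not lower there. With the length trend removed the median of the 48 members was still -1.73, which argues against that trend as the whole cause. Leukocyte RNA in the control library is argued against by the excess of its markers, at most 0.717 FPKM (Cd68) against a median excess of 8.59 for the members. Virus or shRNA that both virus libraries received, acting alone, does not account for the whole pattern either, since the median in the glucose library was -0.11 (quartiles -0.51 to 0.26). Culture or handling of 1 library, with 1 library per condition, and a fall with virus or shRNA that added glucose undid, with a median of 1.56 between the libraries with and without glucose, cannot be told apart and may each be the cause.

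Enrichment over mt-Co2 to mt-Nd4l was lower in both conditions labelled sh-METTL3, where Mettl3 RNA was not lower. Loss over mitochondrial RNA as a whole is argued against by the other peaks, whose median in the authors' deposited table was 1.06 for glucose against control. Counts of these genes in the library labelled sh-METTL3 were at least 1.12 times the control's (mt-Atp6), which argues against too few RNA reads. The glucose library had at least 1.14 times (mt-Co3) for the genes other than mt-Atp8 and mt-Atp6, which argues the same way. For mt-Atp8, at 0.353 times, and mt-Atp6 too few reads stay open, although 5139 and 57504 counts remained there. Such counts may not be of the input behind the peaks, may be shared with the copy, and leave out pulled-down reads. They cannot show how many reads the peak calls had. Reads shared with the copy on chromosome 1 could be the source and cannot be told apart from a change in m6A. For glucose against control, 71.4% (5 of 7) of the peaks that overlap copied genes were below -1 in the authors' deposited table. Those at the end of mt-Co1 (1.06) and over most of mt-Nd4 (0.63) were not. For sh-METTL3 against control, all 6 peaks inside this part were below -1 in the authors' deposited table. The peak over most of mt-Nd4 stood at -0.53 there. Peaks over the copy itself numbered 3 in the control list, 0 in the list labelled sh-METTL3 and 2 in the glucose list. A change in m6A of this part is a hypothesis that sites counted by uniquely placed reads would test.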
